A study of Mus musculus with 24 samples.

How the data were processed

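Microarrays measured RNA of mouse naive CD4 T cells from TRIM28 knockout mice (KO) and wild-type littermates (WT). Per the labels' protocols, the cells were enriched on magnetic beads, sorted by flow cytometry and stimulated with bound anti-CD3 and soluble anti-CD28, RNA was taken with a column kit that included a DNase step, and biotin-labelled cDNA was run on an Affymetrix GeneTitan instrument. The sort gate is not given in the sources used here. The 24 arrays fall into 8 groups of 3 by genotype and time (0, 4, 24 and 72 h), which, with the numbers 1 to 3, come from the sample titles.

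The deposited table holds log2 values made by the authors with RMA in the oligo package under R 3.1.0, per the submitters' processing notes, for 41345 probe sets. The versions of RMA and oligo, the probe set level, filters and any batch handling are not given in the sources used here. RMA corrects background, gives all arrays the same distribution and summarises probes, so it hides a change shared by all genes and compresses low signals. There are no detection calls. Array medians lay between 3.59 and 3.77, the highest correlation between 2 arrays was 0.992 and the median within a group 0.99, and 0 columns were identical. No batch or date was given, so none was tested, and the number of arrays limits the precision.

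Probe sets were named from the platform annotation, which lists 25335 of them. Of these 23521 have 1 gene symbol and 1814 several, and 16010 further probe sets have no gene listed there. By Entrez ID, 23328 were matched to a RefSeq table (GRCm38.p6), used only for current names and for gene order. For the 1082 genes with several probe sets the one with the highest mean over all arrays was used, which left 22180 genes. Probe sets with several genes or none were tested apart.

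Differential expression was tested with limma 3.58.1 in R 4.3.3. A model with 8 group means was fitted to all 24 arrays, so that all groups share 1 estimate of the spread (16 residual and 8.81 prior degrees of freedom, 24.8 in all), with eBayes and a mean-variance trend. Contrasts were KO against WT at each time, each time against 0 h in each genotype, and the interaction, the difference between the KO and the WT response. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes count as past the threshold. The limma, camera and fry tests are two-sided, whereas the splits of the arrays and the random draws of neighbouring genes count only results at least as large and are one-sided. The p-values measure the spread between these arrays, which the labels do not tie to separate animals.

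Gene lists were tested with limma's camera, which compares a list with all other genes, at a preset correlation of 0.01, with adjustment over the tests of each family, and again with a correlation estimated per list. Fry, which tests whether a list's genes move one way on balance, was a further alternative. The 32 lists, fixed before the data were examined, hold silencing factors (TRIM28, HP1 and partners), imprinted genes, germline and early-embryo genes, zinc finger genes named Zfp and a number, clustered protocadherins, early T cell receptor response, naive and quiescence, T cell identity, cytokines and chemokines, T helper 1, T helper 2, T helper 17, regulatory T cell, inhibitory receptor, effector and memory, glycolysis, oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, amino acid transport with ATF4 targets, PI3K with AKT and mTOR, cholesterol and fatty acid synthesis, MYC targets with ribosome biogenesis, cell cycle, p53 targets, interferon-stimulated and apoptosis genes, and markers of B cells, CD8 T cells, myeloid cells, natural killer and innate lymphoid cells, and erythroid cells with platelets. Some genes are in more than 1 list.

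The genes named were chosen by a rule fixed before the data were examined. Trim28 comes first at every time. For each KO and WT comparison the 6 highest and 6 lowest changes past the threshold without overlap of the arrays were taken, and from each list with at least 3 members past the threshold up to 2 with the largest absolute change. For each stimulation the 3 highest and 3 lowest changes in WT were taken, for each interaction the 4 highest and 4 lowest, and of the genes called in 1 direction at all 4 times the 10 with the largest smallest absolute change. A fixed set of reference genes (Cd4, Cd3e, Il2, Il2ra, Cd69, Cd44, Myc, Slc2a1, Il17a, Ifng, Il4, Foxp3, Tbx21, Gata3 and Mki67) may be given whether or not past the threshold, and further members of that set are not reported here. Predicted genes, small RNAs and receptor segment genes were counted but not named unless fewer than 6 others were left. Genes outside the rule are named only where said, after their values were seen.

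The alternatives were the mean of a gene's probe sets, leaving out genes below the 40th percentile of mean level (3.24 on the log2 scale, 13308 genes left), quantile normalization of the gene table again, arrays centred on their medians, eBayes without the trend or robust, array weights, a fit of only the groups compared, a 2-fold minimum, the replicate number as a block, genotype and number together as a random or fixed block (consensus correlation -0.00752 for the random block), and leaving out each array in turn. The other alternatives, added after the data were seen, used arrays numbered 1 and 2 alone, or KO array 2 as the sole KO array. The replicate numbers paired the arrays, by a correlation of their deviations from the group means above 0.1 in every pair, only for KO cells between 0 and 24 h (0.167, 0.122 and 0.177). The pairing comes from the data, since the labels do not say what a number stands for. Splits of the arrays into other groups of the same sizes were counted, all 10 of them for 3 arrays against 3 and 100 drawn at random elsewhere.

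The fits were tested on simulated data for KO against WT at 24 h over 22180 genes. Changes of 0.5, 1 and 2 on the log2 scale were recovered for 58.8%, 93.9% and 100% of the changed genes, with 9 false calls among 21959 unchanged genes. A list shifted by 0.4 was called (adjusted p = 1.18e-30 in camera) with 0 other lists called. The simulated noise was drawn independently for each gene, so the simulation does not test list calls among correlated genes.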

Results

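Affymetrix microarrays measured mRNA levels in mouse naive CD4 T cells that lacked TRIM28 (KO) and in cells of wild-type littermates (WT). TRIM28 is a corepressor that KRAB zinc finger proteins bring to chromatin, where it is linked to histone methylation and the silencing of nearby sequence. The cells were enriched with magnetic beads, sorted by flow cytometry and used at once (0 h) or after stimulation through CD3 and CD28 for 4, 24 or 72 h. The 24 arrays form 8 groups of 3, and 22180 genes were tested. The median of an array lay between 3.59 and 3.77 on the log2 scale. The labels do not say that each array of a group came from a separate animal. The p-values therefore measure the spread between these arrays, part of which may be technical. Arrays numbered 3 had Y-linked levels of male cells in every group, and arrays 1 and 2 Xist levels of female cells. Arrays 3 were therefore not technical repeats of arrays 1 and 2. The main model leaves sex out, and the setting with arrays 1 and 2 alone holds only female levels. The number of arrays limits the precision, and genes near the floor of the scale have compressed fold changes. Levels are log2 intensities with their SD over n = 3 arrays, changes are log2 fold changes of KO over WT with the standard error (SE) of limma's fit, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

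Trim28 itself was lower in KO at every time. Its level was 5.16 ± 0.26 (SD, n = 3) in KO and 7.78 ± 0.07 in WT at 0 h, 5.32 ± 0.15 and 8.42 ± 0.05 at 4 h, 5.61 ± 0.07 and 9.19 ± 0.09 at 24 h, and 5.55 ± 0.32 and 8.64 ± 0.13 at 72 h. The changes were -2.62, -3.10, -3.58 and -3.09 (SE 0.13 each; adjusted p = 1.17e-13, 7.82e-15, 2.53e-16 and 3.46e-15), and KO and WT arrays did not overlap at any time. The sources used here do not give the position of the probe set relative to the deleted part of the gene, so this difference checks the labels only as far as the probes lie in RNA that the deletion removes.

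**Figure D1:**
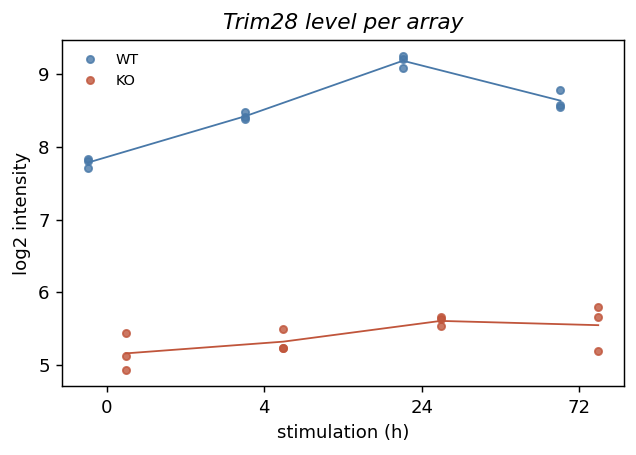
Trim28 level (log2 intensity) on each of the 24 arrays against hours of stimulation, drawn as equally spaced categories; points are arrays and lines join the means of 3 arrays. The WT means rise from 7.78 at 0 h to 9.19 at 24 h and the KO means stay between 5.16 and 5.61.

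The comparison of KO with WT at 0 h asks which genes differed before stimulation. The highest rises were in genes with low WT levels: Upk1b, a membrane protein of the urothelium, was at 8.69 ± 1.39 in KO and 3.40 ± 0.12 in WT (SD, n = 3), a change of 5.30 (SE 0.44). Snai3, a transcription factor of the Snail family, rose by 4.31, the neuronal calcium channel gene Cacna1b by 4.28, Pgpep1l by 4.09, the ciliary gene Lrrc6 by 3.18 and the vomeronasal receptor gene Vmn2r96 by 3.05. The corepressor gene Trim24 rose by 2.35 from a WT level of 8.04 ± 0.09. The lowest changes after Trim28 were in Itgb3, the beta 3 integrin (-1.89, SE 0.14), Sidt1 (-1.37), the motor protein gene Myo10 (-1.17), Muc3a (-1.13) and Prss12 (-1.11). Myc, a transcription factor of growth, fell by 0.54 (SE 0.09, adjusted p = 0.000346), and the interleukin 2 receptor gene Il2ra rose by 0.59 (adjusted p = 0.00231). Cd4 (-0.13, adjusted p = 0.455) and Cd3e (-0.11, adjusted p = 0.45) did not pass the threshold.

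Of the regulatory T cell genes, 7 of 20 rose at 0 h and 0 fell (10 up and 0 down adjusted over the list alone), with a list median of 0.221. The regulatory list gave adjusted p = 5.03e-09, adjusted p = 0.009 with an estimated correlation, over camera's alternatives 3.93e-10 to 0.009. Nrp1, a semaphorin receptor found on regulatory T cells, rose by 2.40 (SE 0.36), while Foxp3, their lineage transcription factor, was 0.76 with adjusted p = 0.113. Of the inhibitory receptor genes, 3 of 14 rose (4 up and 1 down adjusted over the list alone), with Cd200 at 1.54 and Btla at 0.73. The inhibitory list gave adjusted p = 0.00401, adjusted p = 0.153 with an estimated correlation, over camera's alternatives 0.000123 to 0.153. In the fatty acid oxidation list 2 of 19 genes rose (5 up and 0 down adjusted over the list alone), and in the list of naive and quiescence genes 2 of 21 fell (0 up and 3 down adjusted over the list alone). The oxidation list gave adjusted p = 0.0042, adjusted p = 0.163 with an estimated correlation, over camera's alternatives 0.0014 to 0.163. The naive list gave adjusted p = 7.66e-05, adjusted p = 0.216 with an estimated correlation, over camera's alternatives 4.81e-08 to 0.216. Of 336 zinc finger genes named Zfp and a number, 11 rose and 1 fell (14 up and 1 down adjusted over the list alone), Zfp760 by 1.65 and Zfp53 by 1.48. The Zfp list gave adjusted p = 0.0261, adjusted p = 0.436 with an estimated correlation, over camera's alternatives 0.013 to 0.436. Markers of other cells were also higher in KO: the B cell list had a median of 0.746, with 3 of 15 genes risen (10 up and 0 down adjusted over the list alone). The B cell list gave adjusted p = 1.34e-07, adjusted p = 0.255 with an estimated correlation, over camera's alternatives 1.3e-13 to 0.328. The myeloid list had a median of 0.159, with 4 of 19 genes risen (7 up and 0 down adjusted over the list alone) and its neutrophil gene S100a8 at 5.51 ± 1.31 in KO against 3.26 ± 0.53 in WT. The myeloid list gave adjusted p = 0.00194, adjusted p = 0.251 with an estimated correlation, over camera's alternatives 6.45e-05 to 0.251. With KO array 2 as the sole KO array, a setting chosen after these markers were seen, the B cell median was 0.245 (adjusted p = 0.328), the myeloid median 0.135 (adjusted p = 0.15) and the regulatory median 0.24 (adjusted p = 2.24e-05). In the same setting the calls of the inhibitory (adjusted p = 0.114), fatty acid oxidation (0.0683), Zfp (0.134), silencing factor (0.0718) and cholesterol and fatty acid synthesis lists (0.104) also ended. With arrays 1 and 2 alone those of the silencing factor (adjusted p = 0.167), Zfp (0.134), tricarboxylic acid cycle (0.0931), cholesterol and fatty acid synthesis (0.242) and myeloid lists (0.0742) ended.

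At 0 h, 518 genes passed the threshold, 390 higher and 128 lower in KO. The 3 KO and 3 WT arrays did not overlap for 3753 genes, or 16.9%, where chance gives 10%. The count was 314 without WT array 2, 333 without KO array 1, 276 in a fit of only the groups compared, 284 with arrays 1 and 2 alone and 133 with KO array 2 as the sole KO array. Of the 101 genes that changed at least 2-fold 93 were higher and 8 lower, or 92.1% higher in KO. With quantile normalization run again, 523 genes passed, 61% of them higher in KO against 75.3% in the values as deposited, and the Zfp list (adjusted p = 0.166) and the fatty acid oxidation list (0.0532) lost their calls. Leaving out 1 array of this time also ended the calls of the Zfp list (0.0699 without WT array 3, 0.0783 without KO array 3) and of the myeloid list (0.0538 without KO array 3). The lists of silencing factors (adjusted p = 0.0383), tricarboxylic acid cycle genes (0.0475) and cholesterol and fatty acid synthesis genes (0.0412) passed too, and lost their calls with an estimated correlation (adjusted p = 0.397, 0.456 and 0.469). They also lost them without WT array 1 (0.206, 0.189 and 0.052), without KO array 2 (0.0804, 0.17 and 0.0547), without WT array 3 (0.0586 for silencing and 0.267 for cholesterol), without KO array 3 (0.144 for silencing and 0.151 for the cycle genes) and without KO array 1 (0.0653 for cholesterol). The call of the cycle genes further ended without WT array 1 at 4 h, KO array 1 at 4 h, KO array 1 at 24 h or WT array 2 at 72 h, where adjusted p lay between 0.0502 and 0.0581. The 1 gene of the synthesis list past the threshold, Mvd, named after its values were seen, rose by 0.87, against the direction of its list.

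At 4 h the comparison asks which genes differed early in stimulation. Usp18, a protease that restrains interferon signalling, rose by 3.11, from 5.09 ± 0.11 in WT to 8.20 ± 0.21 in KO (SD, n = 3), beside Pgpep1l (4.36), Cacna1b (3.78), Lrrc6 (3.27), the Src family kinase gene Yes1 (2.90) and the glutathione transferase gene Gstt2 (2.85). The lowest changes after Trim28 were in Spin4 (-1.68, SE 0.15), the chemokine receptor gene Ccr4 (-1.57, SE 0.16), the heat shock genes Hspa1b (-1.43) and Hspa1a (-1.39), and Raph1 (-1.24). Genes of cholesterol and fatty acid synthesis fell together: 12 of 21 fell and 0 rose (1 up and 15 down adjusted over the list alone), with a median of -0.463. The synthesis list gave adjusted p = 7.11e-16, adjusted p = 0.011 with an estimated correlation, over camera's alternatives 2.04e-19 to 0.011. Insig1, which holds back the sterol regulators, was at -1.04 (SE 0.12) and the squalene epoxidase gene Sqle at -1.01 (SE 0.13). In the fatty acid oxidation list 5 of 19 genes rose and 0 fell (6 up and 0 down adjusted over the list alone), led by the medium-chain dehydrogenase gene Acadm at 1.80 (SE 0.07) and the thiolase gene Acaa2 at 1.02. The oxidation list gave adjusted p = 3.88e-07, adjusted p = 0.011 with an estimated correlation, over camera's alternatives 2.25e-13 to 0.011.

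Of the regulatory T cell genes 8 of 20 rose and 1 fell at 4 h (9 up and 2 down adjusted over the list alone), with Nrp1 at 2.17 and the transcription factor gene Ikzf4 at 1.01. The regulatory list gave adjusted p = 0.000481, adjusted p = 0.0946 with an estimated correlation, over camera's alternatives 0.000124 to 0.0946. The inhibitory receptor list had 4 of 14 genes risen (5 up and 0 down adjusted over the list alone), among them Cd200 (1.23) and Ctla4 (0.83). The inhibitory list gave adjusted p = 0.000819, adjusted p = 0.0946 with an estimated correlation, over camera's alternatives 3.59e-05 to 0.0946. Of the effector and memory genes 7 of 24 rose (7 up and 0 down adjusted over the list alone). The memory list gave adjusted p = 0.000771, adjusted p = 0.148 with an estimated correlation, over camera's alternatives 2.75e-05 to 0.148. Interferon-stimulated genes rose in 6 of 30 cases (7 up and 0 down adjusted over the list alone). The interferon list gave adjusted p = 0.000481, adjusted p = 0.436 with an estimated correlation, over camera's alternatives 2.11e-05 to 0.436. MYC target and ribosome biogenesis genes fell in 3 of 26 cases (0 up and 4 down adjusted over the list alone), such as the pseudouridine synthase gene Dkc1 at -0.29. The ribosome biogenesis list gave adjusted p = 5.63e-07, adjusted p = 0.233 with an estimated correlation, over camera's alternatives 1.19e-08 to 0.233. The B cell markers had a median of 0.521 with 0 of 15 past the threshold (2 up and 0 down adjusted over the list alone), and 0.282 with KO array 2 as the sole KO array (adjusted p = 0.289). The B cell list gave adjusted p = 9.94e-05, adjusted p = 0.399 with an estimated correlation, over camera's alternatives 5.68e-07 to 0.399. Of the myeloid markers 3 of 19 rose, without a call of the list (adjusted p = 0.0728): S100a8 (1.99, adjusted p = 0.00865), S100a9 (1.46, adjusted p = 0.0089) and, named after its values were seen and not refitted under the alternatives, Lyz2 (0.97). The S100a8 call ended without KO array 1 (1.56) and with robust eBayes, the S100a9 call without KO array 1 (1.22) or WT array 1 (1.26), and both with arrays 1 and 2 alone (1.955 and 1.495) or KO array 2 as the sole KO array (0.72 and 0.65). Cd4 (0.01) and Il2 (0.27, adjusted p = 0.493) did not pass the threshold.

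In all, 917 genes passed at 4 h, 732 higher and 185 lower, and 3597 genes (16.2%, chance 10%) had arrays that did not overlap. A fit of only the groups compared called 309 genes, 269 higher and 40 lower. Without KO array 1 the count was 601, with arrays 1 and 2 alone 562 and with KO array 2 as the sole KO array 238. At least 2-fold changes were found in 100 genes, 90 higher and 10 lower. With quantile normalization run again the count was 743, with 66.2% higher in KO against 79.8%. The lists named Zfp (0.00739), naive and quiescence (0.00835), T helper 1 (0.0299), T helper 2 (0.0475) and PI3K, AKT and mTOR (0.0321) passed as well, all higher in KO except T helper 2, but not with an estimated correlation (adjusted p = 0.348, 0.387, 0.207, 0.255 and 0.328). Their calls ended on leaving out WT array 1 (Zfp 0.0792, T helper 2 0.0653, PI3K 0.0647), WT array 2 (T helper 2 0.0555), WT array 3 (naive 0.214, T helper 1 0.078, T helper 2 0.0688, PI3K 0.0723), KO array 1 (T helper 1 0.0743, T helper 2 0.153), KO array 2 (PI3K 0.0566) or KO array 3 (T helper 2 0.0637). The T helper 2 call also ended without WT array 1, 2 or 3 at 24 h or KO array 1 at 72 h, with adjusted p between 0.051 and 0.06, and quantile normalization run again ended the Zfp (0.258), T helper 1 (0.0876) and PI3K (0.202) calls. With KO array 2 as the sole KO array the calls of T helper 1 (adjusted p = 0.0763) and T helper 2 (0.466) ended, as did that of the B cell list, and with arrays 1 and 2 alone those of the naive (0.0857), T helper 1 (0.0944), T helper 2 (0.0944) and PI3K lists (0.0936).

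At 24 h Il2, the growth factor made by activated T cells, was at 7.91 ± 0.34 in KO and 9.91 ± 0.03 in WT (SD, n = 3), a change of -1.996 (SE 0.18, adjusted p = 1.99e-08). The cytokine gene Il1a fell by 3.25 to a KO level of 2.25 ± 0.05, and Pdgfb (-2.29), the chemokine gene Ccl3 (-1.77) and Spin4 (-1.74) were also among the lowest. The highest rises were in Pgpep1l (4.71), Ccdc152 (3.54), Ly6d (3.06), the glutathione transferase gene Gstt1 (3.04), Usp18 (2.85) and the meiotic gene M1ap (2.56). Naive and quiescence genes were higher in KO: 12 of 21 rose and 0 fell (15 up and 0 down adjusted over the list alone), with a median of 0.396. The naive list gave adjusted p = 1.61e-16, adjusted p = 0.011 with an estimated correlation, over camera's alternatives 2.32e-18 to 0.011. S1pr1, the receptor for exit from lymph nodes, rose by 1.55 (SE 0.17) and the quiescence factor gene Klf2 by 1.24 (SE 0.18). Regulatory T cell genes rose in 8 of 20 cases and fell in 0 (8 up and 0 down adjusted over the list alone), with Foxp3 at 1.63 (SE 0.24) and Nt5e, which encodes CD73, at 1.19. The regulatory list gave adjusted p = 2.43e-07, adjusted p = 0.011 with an estimated correlation, over camera's alternatives 1.46e-08 to 0.011. Of the fatty acid oxidation genes 3 of 19 rose (3 up and 0 down adjusted over the list alone), Acadm by 1.81 and the carnitine transferase gene Cpt1a by 0.54. The oxidation list gave adjusted p = 3.6e-05, adjusted p = 0.0371 with an estimated correlation, over camera's alternatives 1.13e-07 to 0.0371.

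Lists of growth and metabolism genes were lower in KO at 24 h. Of the MYC target and ribosome biogenesis genes 23 of 26 fell and 0 rose (0 up and 24 down adjusted over the list alone), with a median of -0.363, and Myc itself fell by 0.44 (SE 0.09). The ribosome biogenesis list gave adjusted p = 1.29e-15, adjusted p = 0.0681 with an estimated correlation, over camera's alternatives 8.41e-17 to 0.0681. Cell cycle genes fell in 7 of 35 cases (0 up and 15 down adjusted over the list alone). The cell cycle list gave adjusted p = 8.18e-06, adjusted p = 0.168 with an estimated correlation, over camera's alternatives 9.09e-08 to 0.168. Cholesterol and fatty acid synthesis genes fell in 8 of 21 (0 up and 11 down adjusted over the list alone), with Hmgcs1 at -0.59 and Stard4 at -0.54. The synthesis list gave adjusted p = 0.000922, adjusted p = 0.255 with an estimated correlation, over camera's alternatives 6.39e-05 to 0.255. Amino acid transport and ATF4 target genes fell in 6 of 27 (0 up and 13 down adjusted over the list alone). The amino acid list gave adjusted p = 0.000552, adjusted p = 0.281 with an estimated correlation, over camera's alternatives 0.000144 to 0.281. In the early T cell receptor response list 12 of 30 genes fell and 1 rose (3 up and 17 down adjusted over the list alone), with Crtam at -1.21. The receptor response list gave adjusted p = 6.17e-05, adjusted p = 0.225 with an estimated correlation, over camera's alternatives 8.27e-08 to 0.225. The glucose transporter gene Slc2a1 fell by 0.38 and the hexokinase gene Hk2 by 0.67, and Tbx21, the T helper 1 transcription factor, was at -0.74 (adjusted p = 0.00472).

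T cell identity and receptor signalling genes rose in 9 of 17 cases and fell in 1 (9 up and 2 down adjusted over the list alone), with the adhesion gene Cd2 at 0.77 and the kinase gene Prkcq at 0.63. The identity list gave adjusted p = 7.45e-07, adjusted p = 0.0946 with an estimated correlation, over camera's alternatives 3.14e-08 to 0.0946. Effector and memory genes rose in 6 of 24 and fell in 2 (7 up and 2 down adjusted over the list alone). The memory list gave adjusted p = 0.000771, adjusted p = 0.148 with an estimated correlation, over camera's alternatives 0.000114 to 0.148. Interferon-stimulated genes rose in 9 of 30, and 1, the RNA sensor gene Ifih1, fell by 1.52 (11 up and 1 down adjusted over the list alone). The interferon list gave adjusted p = 7.45e-06, adjusted p = 0.326 with an estimated correlation, over camera's alternatives 2.72e-07 to 0.326. B cell markers had a median of 0.574 with 3 of 15 risen (7 up and 0 down adjusted over the list alone). The B cell list gave adjusted p = 8.84e-06, adjusted p = 0.348 with an estimated correlation, over camera's alternatives 1.72e-08 to 0.348. The CD8 and natural killer marker lists were not called (adjusted p = 0.312 and 0.633), with 1 gene of each fallen, Cd8b1 (-0.41) and Eomes (-0.92), named after their values were seen and not refitted under the alternatives.

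The 24 h comparison called 2501 genes, 865 higher and 1636 lower in KO, with non-overlapping arrays for 6034 genes (27.2%, chance 10%). Among the 129 genes that changed at least 2-fold the direction was the other way, with 104 higher and 25 lower, or 80.6% higher in KO against 34.6%. The count was 1269 without KO array 1 and 472 with KO array 2 as the sole KO array, 223 higher and 249 lower. With quantile normalization run again 2159 genes passed, 1150 higher and 1009 lower, so that 53.3% were higher in KO against 34.6% in the values as deposited. The lists of tricarboxylic acid cycle (6 of 23 fell; 2 up and 9 down adjusted over the list alone), glycolysis (6 of 21 fell; 0 up and 7 down adjusted over the list alone) and oxidative phosphorylation genes (7 of 68 fell and 2 rose; 2 up and 10 down adjusted over the list alone) were lower in KO with adjusted p = 0.0103, 0.0475 and 0.0467. Their calls ended with an estimated correlation (adjusted p = 0.348, 0.387 and 0.549) and with quantile normalization run again (0.108, 0.0836 and 0.334), and the last pair also with arrays centred on their medians (0.0564 and 0.0561). The glycolysis call ended without WT array 1 (0.086), WT array 2 (0.0732) or KO array 1 (0.121), and, with adjusted p from 0.0501 to 0.0643, without WT arrays 1 to 3 or KO array 1 at 4 h or WT arrays 1 to 3 or KO array 3 at 72 h. The oxidative phosphorylation call ended without WT array 2 (0.0783), WT array 3 (0.0623), KO array 1 (0.0525), KO array 3 (0.11) or WT array 1 at 0 h (0.052). With KO array 2 as the sole KO array the calls of glycolysis (adjusted p = 0.0683) and oxidative phosphorylation (0.234) ended, and with arrays 1 and 2 alone that of oxidative phosphorylation (0.114).

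At 72 h interferon-stimulated genes were lower in KO: 27 of 30 fell (1 up and 28 down adjusted over the list alone), with a median of -1.35. The interferon list gave adjusted p = 4.24e-59, adjusted p = 0.00146 with an estimated correlation, over camera's alternatives 1.52e-103 to 0.00146. The antiviral gene Rsad2 was at 5.61 ± 0.08 in KO and 8.84 ± 0.12 in WT (SD, n = 3), a change of -3.23 (SE 0.17), and Cxcl10, an interferon-induced chemokine, was at -3.28, Ifi204 at -2.94 and Phf11a at -3.09. The 1 member that rose, Ly6e (0.27, adjusted p = 0.012), was named after its values were seen. T helper 1 genes fell in 11 of 17 cases and rose in 1 (1 up and 11 down adjusted over the list alone), with a median of -0.74. The T helper 1 list gave adjusted p = 6.43e-18, adjusted p = 8.03e-05 with an estimated correlation, over camera's alternatives 8.55e-36 to 8.03e-05. Granzyme B (Gzmb), a killing protease, was at 7.72 ± 0.21 in KO and 10.56 ± 0.10 in WT, the transcription factor genes Eomes and Tbx21 fell by 3.15 and 2.35 (SE 0.17 and 0.17), and Ifng fell by 0.93 (SE 0.13). The 1 T helper 1 gene that rose, Hopx (1.07, adjusted p = 0.000267), was also named after its values were seen. Among the p53 targets 5 of 22 fell and 1 rose (1 up and 6 down adjusted over the list alone), with the cell death gene Perp at -2.67 and the kinase gene Plk2 at -1.94. The p53 list gave adjusted p = 8.12e-05, adjusted p = 0.0257 with an estimated correlation, over camera's alternatives 2.37e-06 to 0.0257.

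Other groups were higher in KO at 72 h. Cholesterol and fatty acid synthesis genes rose in 9 of 21 cases and fell in 0 (14 up and 0 down adjusted over the list alone), with a median of 0.318, including Nsdhl (0.67) and the fatty acid synthase gene Fasn (0.66). The synthesis list gave adjusted p = 5.6e-12, adjusted p = 0.0217 with an estimated correlation, over camera's alternatives 1.05e-13 to 0.0217. Foxp3 rose by 2.49, from 5.44 ± 0.46 in WT to 7.93 ± 0.40 in KO, and 5 of 20 regulatory T cell genes rose while 0 fell (7 up and 2 down adjusted over the list alone), Lrrc32, which binds latent TGF-beta, by 1.71. The regulatory list gave adjusted p = 0.00222, adjusted p = 0.149 with an estimated correlation, over camera's alternatives 0.000554 to 0.149. Highest were M1ap (3.96), Pgpep1l (3.42), the chemokine gene Ccl22 (2.74), Ly6d (2.53) and the deubiquitinase gene Otud1 (2.53). Of the silencing factors 6 of 23 rose and 1, Trim28, fell (7 up and 1 down adjusted over the list alone), with the histone methyltransferase gene Setdb1, whose product works with TRIM28, at 1.43 (SE 0.07). The silencing list gave adjusted p = 0.000552, adjusted p = 0.179 with an estimated correlation, over camera's alternatives 0.000214 to 0.179. Acadm rose by 2.39 (SE 0.07), while the fatty acid oxidation list as a whole had adjusted p = 0.22, a median of -0.0506 and a mean of 0.148. Oxidative phosphorylation genes rose in 7 of 68 (10 up and 0 down adjusted over the list alone), with Ndufa4 at 0.52. The oxidative phosphorylation list gave adjusted p = 1.81e-06, adjusted p = 0.168 with an estimated correlation, over camera's alternatives 9.97e-08 to 0.168. Cell cycle genes rose in 6 of 35 and fell in 1 (9 up and 1 down adjusted over the list alone), and T cell identity genes rose in 6 of 17 (8 up and 2 down adjusted over the list alone), with the kinase gene Zap70 at 0.49. The cell cycle list gave adjusted p = 0.000686, adjusted p = 0.281 with an estimated correlation, over camera's alternatives 1.92e-06 to 0.281. The identity list gave adjusted p = 0.000481, adjusted p = 0.225 with an estimated correlation, over camera's alternatives 3.68e-05 to 0.225.

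Amino acid transport and ATF4 target genes fell at 72 h in 7 of 27 cases and rose in 1 (1 up and 12 down adjusted over the list alone), with the cystine transporter gene Slc7a11 at -1.12. The amino acid list gave adjusted p = 7.22e-06, adjusted p = 0.168 with an estimated correlation, over camera's alternatives 1.54e-07 to 0.168. Il2 did not differ past the threshold at 72 h (0.04, adjusted p = 0.972). Markers of other cells moved both ways. B cell markers had a median of 0.57 (1 of 15 risen; 6 up and 0 down adjusted over the list alone), natural killer and innate lymphoid markers fell in 3 of 11 (0 up and 3 down adjusted over the list alone) with a median of 0.0433, opposite in sign to their mean of -0.47, and that list shares Eomes and Nkg7 with the T helper 1 list. The B cell list gave adjusted p = 0.000165, adjusted p = 0.42 with an estimated correlation, over camera's alternatives 6.25e-07 to 0.42. The natural killer list gave adjusted p = 0.0233, adjusted p = 0.168 with an estimated correlation, over camera's alternatives 8.44e-05 to 0.212. Myeloid markers fell in 3 of 19 (0 up and 3 down adjusted over the list alone) around a median of -0.0147, with Mpeg1, a pore-forming protein of macrophages, at -3.38. The myeloid list gave adjusted p = 0.0176, adjusted p = 0.348 with an estimated correlation, over camera's alternatives 0.000394 to 0.348. Of the 2 CD8 T cell markers 1 fell (0 up and 1 down adjusted over the list alone). The CD8 list gave adjusted p = 0.0383, adjusted p = 0.225 with an estimated correlation, over camera's alternatives 0.0202 to 0.225. The marker that fell was Cd8b1, named after its values were seen, at -0.65.

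The 72 h comparison called 1405 genes, 567 higher and 838 lower in KO, and 5451 genes (24.6%, chance 10%) had arrays that did not overlap. Leaving out any 1 array gave 988 to 1143 genes, and the count was 2249 with array weights, 707 with arrays 1 and 2 alone and 481 with KO array 2 as the sole KO array. Of the 219 genes that changed at least 2-fold 53 were higher and 166 lower, or 24.2% higher in KO against 40.4%. The ribosome biogenesis list also passed at 72 h (1 rose and 1 fell of 26; 1 up and 1 down adjusted over the list alone), not without WT array 3 (0.0603) or KO array 1 (0.102), and the CD8 marker call ended without KO array 3 (0.0826) and the myeloid marker call without KO array 1 (0.053). The ribosome biogenesis list gave adjusted p = 0.019, adjusted p = 0.549 with an estimated correlation, over camera's alternatives 0.0052 to 0.549. With KO array 2 as the sole KO array, the calls of the B cell (0.111), CD8 (0.0683), myeloid (0.0763), natural killer (0.0718), cell cycle (0.0683), T cell identity (0.0666) and ribosome biogenesis (0.248) lists ended, and with arrays 1 and 2 alone those of the CD8 (0.105) and ribosome biogenesis lists (0.0551).

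**Figure D2:**
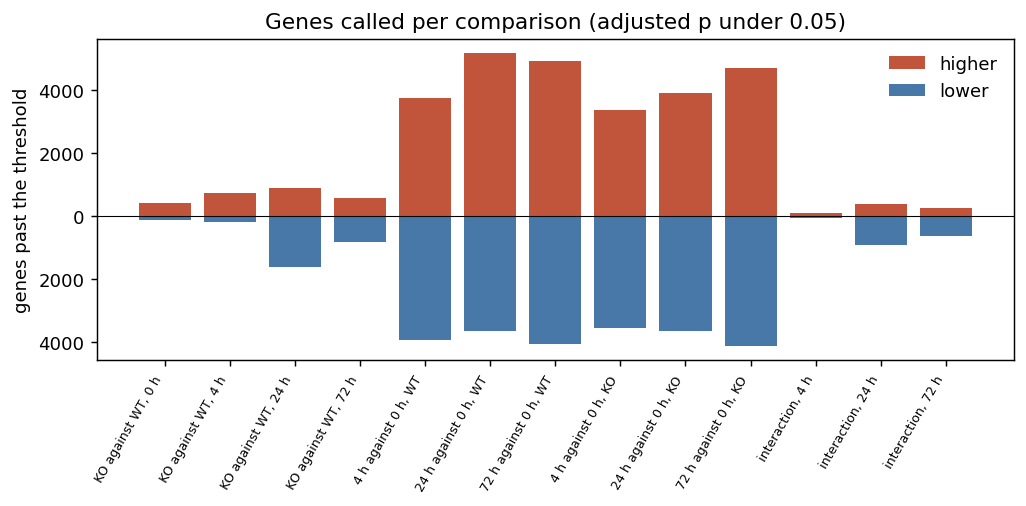
Genes past the threshold (adjusted p under 0.05 in limma) in each of 13 comparisons. Bars above 0 count genes that were higher in the first-named group, or whose interaction was above 0, and bars below 0 those that were lower. KO against WT gives 518, 917, 2501 and 1405 genes at 0, 4, 24 and 72 h, against 7695, 8810 and 8986 for stimulation of WT cells.

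**Figure D3:**
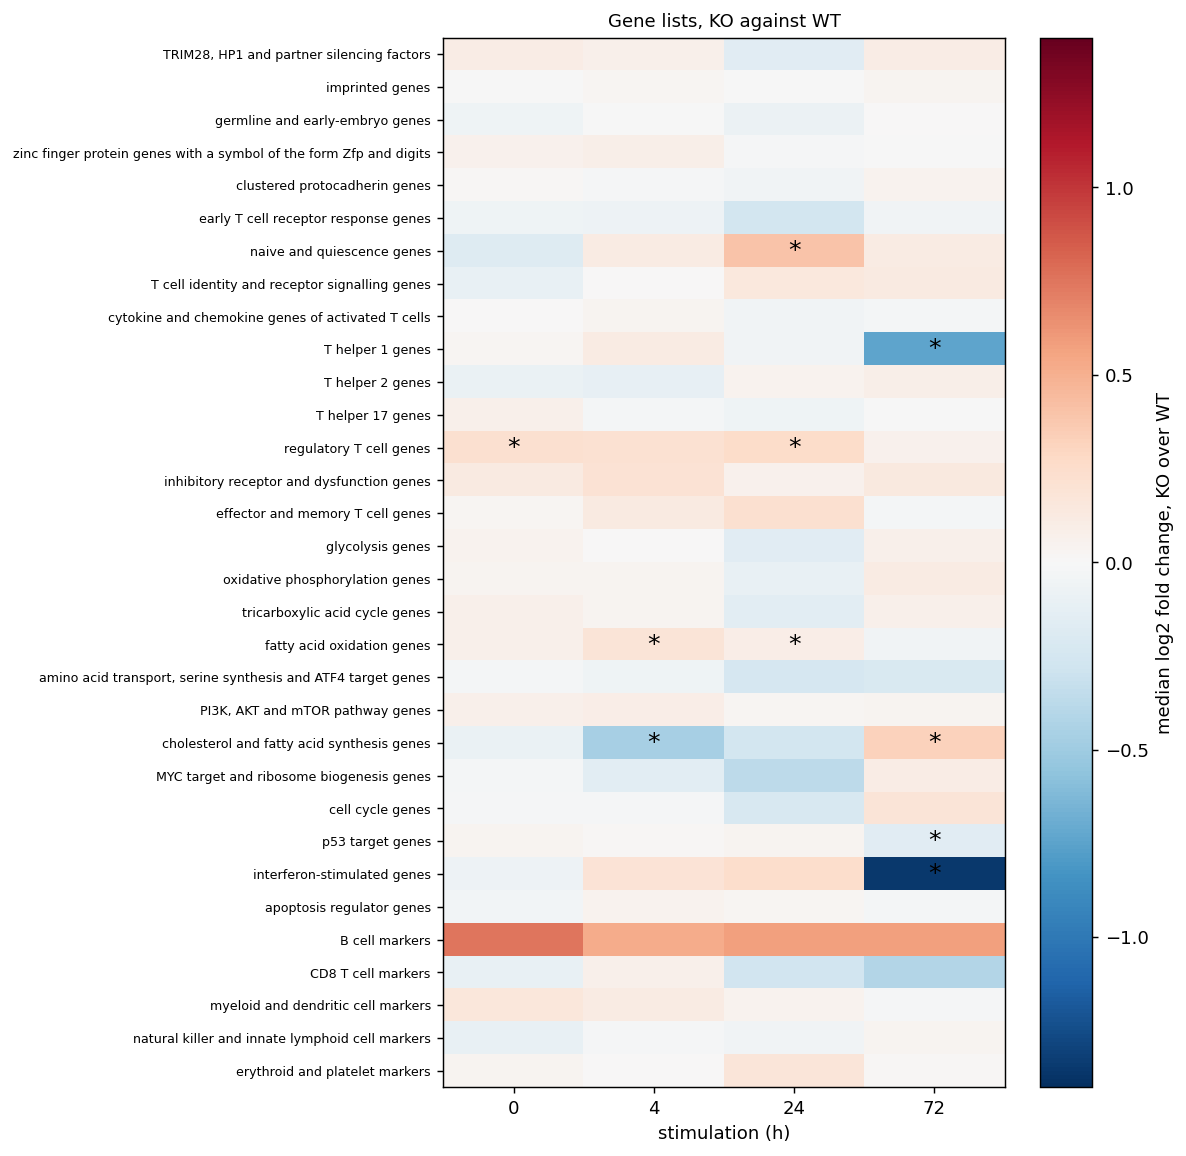
Median log2 fold change of KO over WT for each of 32 gene lists (vertical) at 0, 4, 24 and 72 h (horizontal), with red for higher and blue for lower in KO; a star marks the 10 list calls that hold with an estimated correlation. The lowest median is -1.35 for interferon-stimulated genes at 72 h, and regulatory T cell genes have a star at 0 and 24 h.

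**Figure D4:**
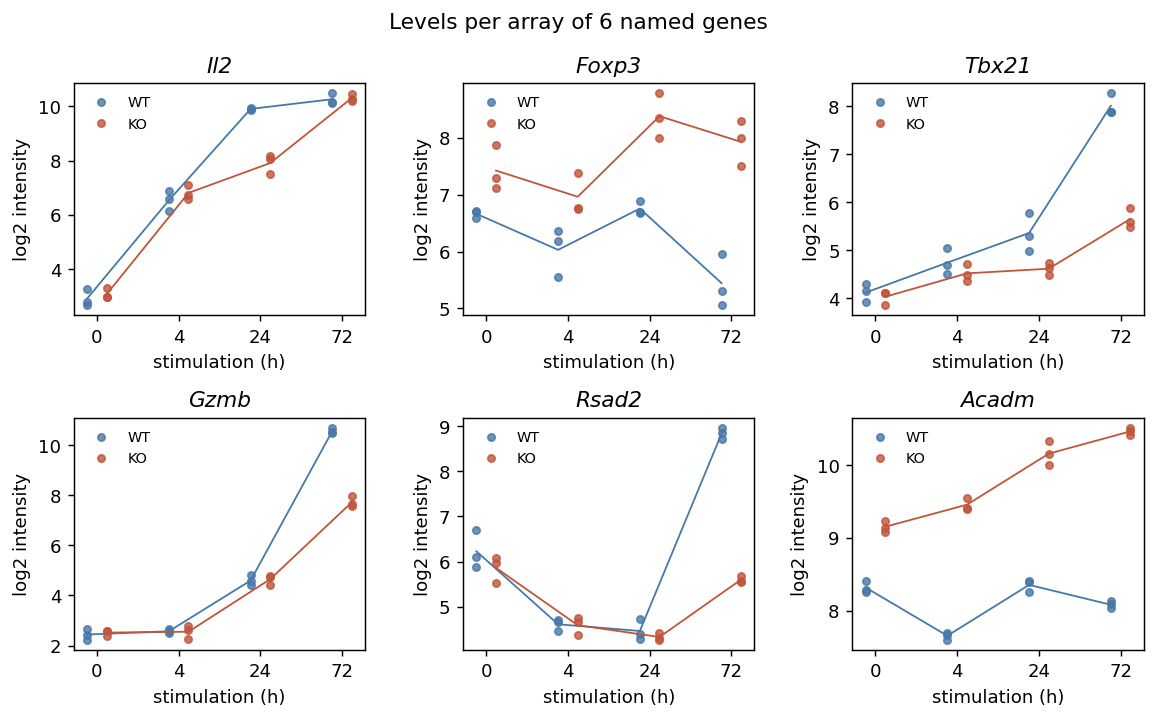
Level (log2 intensity) on each array of Il2, Foxp3, Tbx21, Gzmb, Rsad2 and Acadm against hours of stimulation, drawn as equally spaced categories; points are arrays and lines join the means of 3 arrays. Il2 is lower in KO at 24 h (7.91 against 9.91), Gzmb at 72 h (7.72 against 10.56), and Acadm is higher in KO at all 4 times (9.15 against 8.32 at 0 h).

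Across the 4 times 4153 genes were called at least once, and 49 were called in 1 direction at all 4, 45 of them higher and 4 lower in KO. Independent lists of the same sizes would share 0.0128 and 0.00298 genes. With Trim28, those with the largest smallest change were Pgpep1l (4.09, 4.36, 4.71 and 3.42 at 0, 4, 24 and 72 h), Gstt1 (2.52, 2.55, 3.04 and 1.997), Vmn2r96 (3.05, 2.70, 2.24 and 1.83), Ly6d (2.23, 1.53, 3.06 and 2.53), Klhl6 (1.70, 1.46, 2.10 and 1.63), Yes1 (1.39, 2.90, 1.49 and 1.92), Gstt3 (1.68, 2.28, 1.86 and 1.17), Tenm4 (1.59, 1.54, 1.41 and 1.13) and the mannosidase gene Man1a (1.12, 1.51, 1.08 and 0.96). For Tenm4 1 of its 2 probe sets had the opposite sign at each time. Without KO array 1 at 72 h, Gstt1 at 72 h was 1.65 with adjusted p = 0.0752. Genes higher in KO were shared by 149 between 0 and 4 h (12.9 for independent lists), 292 between 4 and 24 h (28.5) and 176 between 24 and 72 h (22.1). Genes lower in KO were shared by 114 between 24 and 72 h (61.8 for independent lists).

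Of the 128 list tests of KO against WT 53 passed, 10 with an estimated correlation and 47 with limma's fry. No call was made at any time for imprinted genes (lowest adjusted p = 0.502, 24 h), germline and early-embryo genes (0.451, 24 h), clustered protocadherins (0.293, 4 h), T helper 17 genes (0.505, 0 h), cytokine and chemokine genes (0.0522, 72 h), apoptosis regulators (0.0994, 24 h) or erythroid and platelet markers (0.22, 24 h). Median and mean had opposite signs, without a call, at 0 h for the imprinted, germline, early receptor response, cytokine and T helper 1 lists, at 4 h for the silencing factors, germline, T cell identity, T helper 17 and natural killer lists, at 24 h for the germline list and at 72 h for the imprinted, Zfp, T helper 17, fatty acid oxidation and erythroid lists. In the interaction the same held at 4 h for the imprinted, germline, T helper 2, glycolysis, cell cycle and erythroid lists, at 24 h for the imprinted and natural killer lists and at 72 h for the imprinted, germline, fatty acid oxidation and erythroid lists.

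Stimulation of WT cells, compared with 0 h, gives the background against which the KO response was read. At 4 h the semaphorin gene Sema7a rose most (5.95 in WT and 5.26 in KO), with Rgs16 (5.82 and 4.90) and the chemokine receptor gene Ccr8 (5.31 and 5.31), and Slc16a5 (-4.47 and -4.14), Igfbp4 (-4.34 and -4.41) and Rasgrp2 (-3.94 and -3.06) fell most. Early T cell receptor response genes rose in 24 of 30 cases in WT (25 up and 5 down adjusted over the list alone), and MYC target and ribosome biogenesis genes in 26 of 26 (26 up and 0 down adjusted over the list alone). In WT the receptor response list gave adjusted p = 1.07e-17, adjusted p = 0.00732 with an estimated correlation, over camera's alternatives 1.3e-50 to 0.00732. In WT the ribosome biogenesis list gave adjusted p = 2.22e-30, adjusted p = 0.0063 with an estimated correlation, over camera's alternatives 1.01e-59 to 0.0063. Interferon-stimulated genes fell in 29 of 30 at 4 h (0 up and 29 down adjusted over the list alone). In WT the interferon list gave adjusted p = 4.22e-20, adjusted p = 0.0203 with an estimated correlation, over camera's alternatives 4.52e-26 to 0.0203. At 24 h Il2 rose by 6.998 in WT and 4.84 in KO, the replication gene Mcm10 by 5.26 and 4.46 and Cpd by 4.98 and 3.68, while the interferon-inducible genes Ifi208 (-5.61 and -3.45), Ifi213 (-4.80 and -2.65) and Rtp4 (-4.78 and -3.45) fell. Cell cycle genes rose in 34 of 35 at 24 h (34 up and 0 down adjusted over the list alone), with Mki67 at 4.27 in WT and 3.54 in KO, and oxidative phosphorylation genes in 58 of 68 (59 up and 3 down adjusted over the list alone). In WT the cell cycle list gave adjusted p = 1.64e-29, adjusted p = 0.00153 with an estimated correlation, over camera's alternatives 1.4e-77 to 0.00153. In WT the oxidative phosphorylation list gave adjusted p = 2.88e-15, adjusted p = 0.0125 with an estimated correlation, over camera's alternatives 1.29e-15 to 0.0125.

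At 72 h Gzmb rose by 8.12 in WT and 5.20 in KO, Il2 by 7.36 and 7.24, and Cth, an enzyme of cysteine synthesis, by 6.54 and 5.75. Slc16a5 (-5.75 and -5.87), Rasgrp2 (-5.57 and -4.76) and Klf2 (-5.17 and -4.38) fell most. Cholesterol and fatty acid synthesis genes rose in 21 of 21 in WT (21 up and 0 down adjusted over the list alone) and 21 in KO, amino acid transport and ATF4 target genes in 26 of 27 (26 up and 0 down adjusted over the list alone), and T helper 1 genes in 14 of 17 with 2 fallen (15 up and 2 down adjusted over the list alone). In WT the synthesis list gave adjusted p = 7.66e-15, adjusted p = 0.00732 with an estimated correlation, over camera's alternatives 8.78e-19 to 0.00732. In WT the amino acid list gave adjusted p = 1.51e-22, adjusted p = 0.00451 with an estimated correlation, over camera's alternatives 2.59e-41 to 0.00451. In WT the T helper 1 list gave adjusted p = 5.71e-07, adjusted p = 0.00533 with an estimated correlation, over camera's alternatives 5.06e-14 to 0.00533. Interferon-stimulated genes rose in 23 of 30 and fell in 5 in WT (23 up and 6 down adjusted over the list alone), and in KO 8 rose and 9 fell (adjusted p = 0.415). In WT the interferon list gave adjusted p = 1.91e-06, adjusted p = 0.202 with an estimated correlation, over camera's alternatives 1.4e-07 to 0.202. Ifng rose by 1.16 in WT (adjusted p = 3.68e-08) and was 0.02 in KO (adjusted p = 0.931). Stimulation changed 7695, 8810 and 8986 genes in WT and 6895, 7546 and 8810 in KO at 4, 24 and 72 h, with non-overlapping arrays for 40.3%, 46.6% and 50.4% of genes in WT (chance 10%). The KO counts were 4125, 4839 and 5821 with KO array 2 as the sole KO array. With quantile normalization run again, 48.2% of the 8872 genes called in WT at 24 h rose, against 58.4%. Of the 192 list tests of stimulation 101 passed, 67 with an estimated correlation and 153 with fry.

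The interaction compares the response of KO with that of WT, so a value above 0 is a larger rise or a smaller fall in KO. At 24 h the response of Il2 was lower in KO by 2.16 (interaction -2.16, SE 0.25, adjusted p = 8.59e-06), and Upk1b (-3.81), Snai3 (-3.13), Il1a (-3.09) and Cacna1b (-2.67) were lowest. Ccdc152 (3.42), M1ap (2.56), Ifi214 (2.35) and Ifi208 (2.16) were highest. Naive and quiescence genes had a higher response in KO, meaning a smaller fall, in 12 of 21 cases (17 up and 0 down adjusted over the list alone), with a median of 0.601. For this response the naive list gave adjusted p = 2.38e-22, adjusted p = 0.00461 with an estimated correlation, over camera's alternatives 3.44e-25 to 0.00461. Mki67 was at -0.73 (adjusted p = 0.0107). In all 1302 genes passed, 367 above and 935 below 0, whereas of the 144 with a difference of at least 2-fold 74 lay above and 70 below 0 (51.4% above). The count was 700 without KO array 1 at 24 h, 779 with arrays 1 and 2 alone and 152 with KO array 2 as the sole KO array (48% above 0), and with quantile normalization run again 976 genes passed, 60.9% above 0 against 28.2%. Of the 5146 genes that rose in WT at 24 h, 839 rose less in KO and 11 more, with a median ratio of the KO to the WT change of 0.66, and among the 3893 that rose in KO 640 rose less and 47 more (0.771). Of the 3664 genes that fell in WT at 24 h, 324 fell less in KO and 22 more (median ratio 0.81), and of the 3653 that fell in KO 257 fell less and 114 more (0.935). At 4 h the median ratio was 0.829 for genes that rose and 0.786 for genes that fell in WT, and 0.924 and 0.912 for those chosen in KO. At 72 h these ratios were 0.88 and 0.911 for genes chosen in WT, and 0.993 and 1.06 for those chosen in KO.

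At 72 h the response of interferon-stimulated genes was lower in KO in 22 of 30 cases (0 up and 27 down adjusted over the list alone), with a median of -1.21, and that of T helper 1 genes in 9 of 17, with 2 higher (2 up and 9 down adjusted over the list alone) and a median of -0.709. For this response the interferon list gave adjusted p = 6.83e-42, adjusted p = 0.00461 with an estimated correlation, over camera's alternatives 2.07e-65 to 0.00461. For this response the T helper 1 list gave adjusted p = 1.38e-11, adjusted p = 0.000986 with an estimated correlation, over camera's alternatives 2.59e-20 to 0.000986. Tbx21 was at -2.26 (SE 0.24) and Ifng at -1.14 (SE 0.19). The p53 target list was lower, with 3 of 22 genes past the threshold (1 up and 6 down adjusted over the list alone). For this response the p53 list gave adjusted p = 0.000137, adjusted p = 0.0396 with an estimated correlation, over camera's alternatives 6.34e-06 to 0.0396. Cholesterol and fatty acid synthesis genes had a higher response in 7 of 21 (14 up and 0 down adjusted over the list alone), with a median of 0.507. For this response the synthesis list gave adjusted p = 3.33e-11, adjusted p = 0.0396 with an estimated correlation, over camera's alternatives 3.91e-14 to 0.0396. Foxp3 was at 1.73 (SE 0.34). Lowest were Upk1b (-4.92), Cacna1b (-4.03), Snai3 (-3.81) and Mpeg1 (-3.47), and highest M1ap (3.95), Ccl22 (2.63), Otud1 (2.47) and St6galnac2 (2.10). The Ccl22 call ended without WT array 2 (2.44, adjusted p = 0.0532) or KO array 1 (2.05, 0.0721). In all 868 genes passed, 234 above and 634 below 0, and with quantile normalization run again 936, of which 42.5% lay above 0 against 27%. Of the 274 with a difference of at least 2-fold 45 lay above and 229 below 0, and the count was 451 with arrays 1 and 2 alone and 260 with KO array 2 as the sole KO array.

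At 4 h 161 genes passed, 99 above and 62 below 0, and 12 of 100 splits of the arrays, the real one included, gave as many. The count was 79 in a fit of only the groups compared, 76 with arrays 1 and 2 alone and 29 with KO array 2 as the sole KO array, and of the 50 with a difference of at least 2-fold 24 lay above and 26 below 0. Usp18 (2.23), Otud1 (1.94), Yes1 (1.51) and the reductase gene Akr1b10 (1.43) were highest and Upk1b (-4.37), Snai3 (-2.83), Ccdc102a (-1.97) and Pltp (-1.89) lowest. Of the 96 list tests of the interaction 32 passed, and 5 with an estimated correlation, none of them at 4 h, against 24 with fry.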

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

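Tests of myeloid cells, of CD8 T cells, of more regulatory T cells and of activation markers were chosen only after the result was seen. The single genes and lists given by their response differed between KO and WT past the threshold in the test of the interaction, and the probe sets given are ones that the comparisons of genes do not use. The regulatory T cell values come from KO against WT, and that list did not pass in the interaction (adjusted p = 0.335, 0.668 and 0.407 at 4, 24 and 72 h).

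At 72 h interferon-stimulated genes (median interaction -1.21) and T helper 1 genes (-0.71) had a lower response in KO. Myeloid cells in the WT cultures stay open. Mpeg1, Ctss and Cd68 fell by 3.38, 0.58 and 0.58 in KO. The median change over 19 myeloid markers was -0.0147 (spread 0.0404). Lyz2 (3.004), Tyrobp (3.27), Csf1r (3.28) and Fcer1g (3.42), abundant in such cells, lay at the WT floor and gave no sign of them. CD8 T cells stay open, and the gate and purity of the sort for naive CD4 T cells, which is meant to remove both kinds, are not given in the sources used here: the lower end of the 95% interval of the Cd8a change was -0.544, above the bound set against them, but Cd8a lay at the floor in both genotypes (3.07 in KO and 3.23 in WT) while Cd8b1 was lower in KO (5.79 against 6.45, adjusted p = 0.000356), and the test was judged open after its value was seen. A general delay between 24 and 72 h stays open too, since genes outside both lists reached a median share of 0.711 of the WT rise (648 genes, spread 0.012), between the bounds set for and against a delay, against 0.542 for 36 genes in the lists (spread 0.0334). A lower interferon and T helper 1 response of cells without TRIM28, the biological explanation the design offers, also stays open, as untested.

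Regulatory T cell genes were higher in KO at all 4 times, with a call that held with an estimated correlation at 0 and 24 h. A rise of all activation markers would lift the early response list, but 27 of its genes outside the regulatory list had a median of -0.0944 (spread 0.0744) at 0 h, which argues against a rise of all of them. The list's 30 genes moved both ways, with 5 risen, among them Tnfrsf9 (0.84) and Bhlhe40 (0.73), whose calls ended with KO array 2 as the sole KO array (0.58 and 0.68), and 3 fallen, namely Tnf, Myc and Cd69, the last not without WT array 1 (-0.22), WT array 3 (-0.26), KO array 1 (-0.19) or KO array 2 (-0.26) at 0 h, so that a rise of part of the list stays open. More regulatory T cells among the sorted KO cells may account for the rise: Foxp3, Ikzf2, Ctla4, Tnfrsf18, Gpr83 and Izumo1r had a median of 0.258 (spread 0.0775) with 6 of 6 above 0, short of the mark set for it but not below 0, so that a change in the cells sorted and a change within each cell cannot be told apart from these values. Of these genes Izumo1r and Tnfrsf18 passed the threshold at 0 h, and whether the sort removed regulatory T cells is not given in the sources used here.

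The number of genes with an interaction past the threshold was 161 at 4 h, 1302 at 24 h and 868 at 72 h. At 4 h 12 of 100 splits of the arrays, the real one included, gave as many (highest other 415). Splits that exchange KO and WT mostly at 1 time add the genotype differences of both times. The 161 calls are therefore neither set apart from chance nor shown to be compatible with it. At 24 and 72 h 1 of 100, the real one, gave as many (highest others 903 and 668), a share under 0.05. The splits keep part of the real genotype differences and exchange arrays without regard to their numbers, so this share does not exclude chance. List calls came to 53 for KO against WT (highest other 38), 32 for the interaction (30) and 101 for stimulation (84). Each was reached by 1 of 100 splits, the real one. These are calls at the preset correlation, against 10, 5 and 67 with an estimated one. The splits keep part of the differences of genotype or time, so chance is not excluded there either. For 3 arrays against 3 the 10 splits are too few for a share under 0.05, with real counts of 518, 917, 2501 and 1405 for KO against WT (highest others 7, 3, 1 and 0), 7695, 8810 and 8986 in WT (2, 1 and 0) and 6895, 7546 and 8810 in KO (1, 2 and 0).

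The named genes whose response was higher in KO at 4 h were Usp18 (2.23), Otud1 (1.94), Yes1 (1.51), Akr1b10 (1.43), Klf3 (1.35), Il18r1 (0.98), Acadm (0.97), Ctla4 (0.67) and Man1a (0.39). Those with a lower response at 4 h were Upk1b (-4.37), Snai3 (-2.83), Ccdc102a (-1.97), Pltp (-1.89), Trim24 (-1.60), Ccr4 (-1.60), Spin4 (-1.42), Irf8 (-1.14) and Il2ra (-0.71). The named genes whose response was higher in KO at 24 h were Ccdc152 (3.42), M1ap (2.56), Ifi214 (2.35), Ifi208 (2.16), Usp18 (1.98), S1pr1 (1.80), Klf2 (1.45), Trp53inp1 (1.099), Bcl2 (0.9951), Acadm (0.97), Cd2 (0.96), Zfp704 (0.91), Pik3ip1 (0.82), Nt5e (0.78), Prkcq (0.73) and Cd3e (0.31). Those with a lower response at 24 h were Upk1b (-3.81), Snai3 (-3.13), Il1a (-3.09), Cacna1b (-2.67), Il2 (-2.16), Pdgfb (-1.998), Spin4 (-1.48), Plk2 (-1.34), Ifih1 (-1.22), Ccl4 (-0.99), Pdcd1 (-0.98), Trim28 (-0.95), Ccl3 (-0.91), Trim24 (-0.79), Ccna2 (-0.78), Asns (-0.73), Mki67 (-0.73), Hmgcs1 (-0.62), Rrp12 (-0.52) and Slc2a1 (-0.40). The named genes whose response was higher in KO at 72 h were M1ap (3.95), Ccl22 (2.63), Otud1 (2.47), St6galnac2 (2.10), Foxp3 (1.73), Acadm (1.55), Ccr6 (1.55), Setdb1 (1.31), Zfp704 (0.97), Nsdhl (0.77), Fasn (0.68), Ets1 (0.58), Ndufa4 (0.55), Cd3e (0.46) and Zap70 (0.42). Those with a lower response at 72 h were Upk1b (-4.92), Cacna1b (-4.03), Snai3 (-3.81), Mpeg1 (-3.47), Cxcl10 (-3.30), Ifi204 (-3.18), Phf11a (-2.94), Gzmb (-2.91), Perp (-2.90), Rsad2 (-2.87), Eomes (-2.68), Tbx21 (-2.26), Irf8 (-1.90), Il6 (-1.87), Nkg7 (-1.77), Plk2 (-1.76), Ccl5 (-1.59), Lag3 (-1.33), Vmn2r96 (-1.22), Ifng (-1.14), Fas (-1.08), Slc7a11 (-0.90) and Ctss (-0.72). The lower response of Upk1b, Snai3 and Cacna1b is a shrinking of their rise in KO at 0 h (5.30, 4.31 and 4.28) from low WT levels. The call of Il2ra at 4 h ended without WT array 1 (-0.69) or 3 (-0.58) or KO array 1 (-0.63) or 2 (-0.65) at 0 h, or WT array 2 (-0.66) or 3 (-0.69) or KO array 1 (-0.60) or 2 (-0.72) at 4 h. That of Cd3e at 24 h ended without WT array 1 (0.26) or KO array 3 (0.29) at 0 h, or WT array 2 (0.26) or KO array 1 (0.25) at 24 h. That of Slc2a1 at 24 h ended without WT array 2 (-0.38) or 3 (-0.37) or KO array 1 (-0.34) or 2 (-0.36) at 0 h, or WT array 1 (-0.31) or KO array 1 (-0.36) or 2 (-0.37) at 24 h. That of Ccl22 at 72 h ended without WT array 2 (2.44) or KO array 1 (2.05) at 72 h.

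The naive and quiescence list (0.60) differed at 24 h, and the cholesterol and fatty acid synthesis (0.51) and p53 target lists (-0.19) at 72 h, all as medians over their genes and past the threshold with an estimated correlation. Probe sets with no gene listed changed between KO and WT in 62, 80, 116 and 108 cases at 0, 4, 24 and 72 h, and probe sets that list several genes in 20, 20, 111 and 101.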

How the results depend on the processing

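The settings that keep arrays 1 and 2 alone, or KO array 2 as the sole KO array, were chosen after the data were seen; the others were fixed before the data were examined. Arrays carry no detection call, so a gene near the floor has a compressed fold change and a missed call there says little. RMA's shared quantiles of probe intensities can hide a change of all genes alike. Among 442 changes of named genes (fewer where a setting leaves some out), the same direction and side of the threshold were found in 426 with array weights, 435 with arrays centred on their medians, 421 with quantile normalization run again, 434 with the mean of probe sets, 433 with robust eBayes, 430 without the trend, 405 with only the groups compared, 418 of 421 without dim genes, 399 with arrays 1 and 2 alone and 288 of 381 with KO array 2 as the sole KO array. Of 186 list calls, 82 held with an estimated correlation, 163 with fry, 166 with quantile normalization run again, 154 without dim genes, 172 with only the groups compared, 168 with arrays 1 and 2 alone and 156 with KO array 2 as the sole KO array. Except where a setting itself uses fewer arrays or a stricter threshold, the cause was not tested.

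Requiring a change of at least 2-fold left 101, 100, 129 and 219 genes for KO against WT at 0, 4, 24 and 72 h, 2011, 2872 and 2903 for stimulation in WT, 1596, 1938 and 2754 in KO, and 50, 144 and 274 for the interaction at 4, 24 and 72 h. A fit of only the groups compared called 276 genes at 0 h, 309 at 4 h and 79 for the interaction at 4 h, and array weights called 2249 at 72 h. An estimated correlation kept 10 list calls for KO against WT, 67 for stimulation and 5 for the interaction, and fry called 153 for stimulation. With arrays 1 and 2 alone the counts were 284, 562 and 707 for KO against WT at 0, 4 and 72 h and 76, 779 and 451 for the interaction at 4, 24 and 72 h. With KO array 2 as the sole KO array, which is then assumed to vary like the other groups, they were 133, 238, 472 and 481 for KO against WT, 4125, 4839 and 5821 for stimulation in KO, and 29, 152 and 260 for the interaction.

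With the mean of a gene's probe sets, the sign turned for Slc2a1 (interaction, 72 h) at -0.0138. With quantile normalization run again, the sign turned for Slc2a1 (KO against WT, 0 h) at -0.0262, Cd3e (KO against WT, 4 h) at -0.0263, Foxp3 (24 h against 0 h, WT) at -0.108, Ifng (72 h against 0 h, KO) at -0.0320 and Cd69 (interaction, 72 h) at 0.0334. With arrays centred on their medians, the sign turned for Ifng (72 h against 0 h, KO) at -0.00766. With array weights, the sign turned for Cd4 (KO against WT, 4 h) at -0.0307, Il17a (KO against WT, 24 h) at -0.0107 and Cd69 (interaction, 24 h) at -0.00264. With arrays numbered 1 and 2 alone, the sign turned for Ifng (KO against WT, 24 h) at 0.0608, Il4 (KO against WT, 72 h) at 0.00381, Il17a (4 h against 0 h, WT) at 0.0629, Il17a (72 h against 0 h, WT) at 0.0770, Mki67 (interaction, 4 h) at 0.0596, Cd69 (interaction, 24 h) at -0.0127 and Cd69 (interaction, 72 h) at 0.0268. With KO array 2 as the sole KO array, the sign turned for Ifng (KO against WT, 24 h) at 0.116, Il4 (KO against WT, 24 h) at 0.0322, Il4 (KO against WT, 72 h) at 0.0308, Ifng (4 h against 0 h, KO) at 0.00598, Il4 (24 h against 0 h, KO) at 0.00304, Cd44 (interaction, 24 h) at 0.104, Cd69 (interaction, 24 h) at -0.0485 and Ifng (interaction, 24 h) at 0.0290. None of these changes had passed the threshold. Leaving out 1 array at a time gave 314 to 442 genes for KO against WT at 0 h (518 with all arrays), 601 to 1063 at 4 h, 1269 to 2299 at 24 h and 700 to 1329 for the interaction at 24 h. The lowest counts were without WT array 2 at 0 h, KO array 1 at 4 h and, for the last pair, KO array 1 at 24 h, and without KO array 1 at 0 h the first was 333. Over the same fits the changes that turned sign ranged as follows: Slc2a1 (KO against WT, 0 h) -0.0370 to 0.0960, Il17a (4 h against 0 h, WT) -0.180 to 0.0741, Il17a (24 h against 0 h, WT) -0.238 to 0.0155, Il17a (72 h against 0 h, WT) -0.188 to 0.0662, Il4 (72 h against 0 h, WT) -0.00573 to 0.0555, Foxp3 (interaction, 4 h) -0.0676 to 0.395, Il2 (interaction, 4 h) -0.0962 to 0.281 and Mki67 (interaction, 4 h) -0.159 to 0.0619. They were Tbx21 (interaction, 4 h) -0.255 to 0.0132, Cd44 (interaction, 24 h) -0.249 to 0.0161, Cd69 (interaction, 24 h) -0.0513 to 0.0687, Cd69 (interaction, 72 h) -0.0708 to 0.0480, Ifng (4 h against 0 h, KO) -0.119 to 0.0249, Ifng (24 h against 0 h, KO) -0.0635 to 0.112, Il4 (24 h against 0 h, KO) -0.0749 to 0.0135 and Ifng (72 h against 0 h, KO) -0.0407 to 0.103, and further Cd3e (KO against WT, 4 h) -0.0177 to 0.0382, Cd4 (KO against WT, 4 h) -0.0783 to 0.0605, Il17a (KO against WT, 4 h) -0.0120 to 0.0773, Ifng (KO against WT, 24 h) -0.164 to 0.0307, Il17a (KO against WT, 24 h) -0.0709 to 0.118, Il4 (KO against WT, 24 h) -0.0850 to 0.00345, Il17a (KO against WT, 72 h) -0.00194 to 0.0746 and Il2 (KO against WT, 72 h) -0.0277 to 0.153.

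With the replicate number as a block, 567, 966, 2588 and 1426 genes passed for KO against WT, 7737, 8841 and 9018 for stimulation in WT, 6929, 7566 and 8804 in KO, and 179, 1359 and 903 for the interaction. All 442 changes of named genes kept their call under this block, and 5 list calls ended: silencing factors (adjusted p = 0.0512, camera's alternatives 0.0053 to 0.397), tricarboxylic acid cycle (0.0512, 0.00836 to 0.456) and cholesterol synthesis (0.0526, 0.00146 to 0.469) at 0 h, T helper 2 at 4 h (0.0558, 0.0163 to 0.466) and glycolysis at 24 h (0.0526, 0.0174 to 0.387). With genotype and number as a random block 517, 918, 2505 and 1405 genes passed for KO against WT, and the call of Cd79b at 0 h ended (adjusted p = 0.0503, alternatives 0.0107 to 0.901), as did 18 of 186 list calls. The list calls kept were 48 of 53 for KO against WT, 89 of 101 for stimulation and 31 of 32 for the interaction. Those that ended, each with its adjusted p and the range over camera's alternatives, were for KO against WT tricarboxylic acid cycle (0.0947, 0.00836 to 0.456) and cholesterol and fatty acid synthesis (0.0899, 0.00146 to 0.469) at 0 h, glycolysis (0.0532, 0.0174 to 0.387) and oxidative phosphorylation (0.0826, 0.0283 to 0.549) at 24 h and ribosome biogenesis (0.0532, 0.0052 to 0.549) at 72 h. For stimulation they were oxidative phosphorylation (0.117, 0.00846 to 0.437) at 4 h in WT, B cell (0.126, 0.00367 to 0.593) at 24 h in WT and B cell (0.163, 0.00548 to 0.616) at 72 h in WT, and oxidative phosphorylation (0.119, 0.00295 to 0.436) and B cell (0.148, 0.00206 to 0.632) at 4 h in KO, Zfp (0.0735, 0.019 to 0.436), T cell identity (0.0563, 0.0042 to 0.344) and B cell (0.0621, 0.000434 to 0.548) at 24 h in KO and silencing factors (0.0796, 0.0365 to 0.353), fatty acid oxidation (0.117, 0.0127 to 0.154), B cell (0.0972, 0.000817 to 0.568) and myeloid (0.12, 0.00598 to 0.285) at 72 h in KO. The last was T helper 2 (0.0575, 0.0107 to 0.298) in the interaction at 72 h. Deviations of arrays with the same number correlated at over 0.1 in every pair only between 0 and 24 h in KO. Elsewhere the lowest pair lay between 0.0192 and 0.075, so arrays were not paired by number there. Still, 24 of 24 arrays correlated best on average with their own number, and arrays 3 differed in Xist and Y-linked genes.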

Other observations

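The tests of neighbouring genes were fixed before their results were seen, and the values of single genes that follow were picked after they were seen.

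At 72 h several gene groups without a list call held changes in both directions. Of the 14 inhibitory receptor genes 4 rose and 3 fell (adjusted p = 0.185 for the list): Pdcd1, which encodes PD-1, rose by 0.72 (SE 0.14) and Lag3 fell by 0.73 (SE 0.15). Of the 21 naive and quiescence genes 4 rose and 3 fell (adjusted p = 0.293), with the transcription factor gene Ets1 at 0.45 and the interleukin 7 receptor gene Il7r at -1.13. Of the 17 T helper 17 genes 1 rose and 2 fell (adjusted p = 0.965). The chemokine receptor gene Ccr6 rose by 1.61 (KO 5.54 ± 0.21, WT 3.92 ± 0.13, SD, n = 3). Hif1a was at -0.36 (adjusted p = 0.0339), without a refit under the alternatives, and Il12rb1 at -0.67 (adjusted p = 0.0284). The Il12rb1 call ended without WT array 1 (-0.68), 2 (-0.72) or 3 (-0.61) or KO array 2 (-0.65) or 3 (-0.63) at 72 h. Of the 33 cytokine and chemokine genes 9 fell and 2 rose (adjusted p = 0.0522), among them Il6 at -1.98 and Ccl5 at -1.56. The death receptor gene Fas, counted with the apoptosis regulators and the p53 targets, was at -0.74 (SE 0.11).

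Xist and Y-linked genes split the arrays by number in both genotypes and at every time. On arrays numbered 3 Xist lay between 3.03 and 4.79, Kdm5d between 6.42 and 7.41, Eif2s3y between 8 and 8.69 and Uty between 6.12 and 6.87, against 9.61 to 10.3, 2.21 to 2.97, 2.14 to 2.75 and 2.26 to 2.66 on arrays numbered 1 and 2.

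Genes that rose in KO lay side by side more often than chance placed them: 1846 genes higher in KO at 1 or more times held 294 adjacent pairs, against a median of 153 in 10000 random draws of as many genes. Gene families with like symbols, such as Gstt1, Gstt2 and Gstt3, are argued against as the whole source, since 262 pairs remained without them (random draws median 130, highest 168). Permutation draws gave fewer pairs from genes risen in WT at 24 h (median 186, highest 234) or fallen in KO (median 206, highest 239). Both had one-sided permutation p = 1e-04, the least 10000 draws can give. Drawing 1846 of 5140 or 2557 genes breaks up pairs, so neighbourhoods of any regulated set, or of genes differing by genotype, stay open. The genotype itself, transcripts running from 1 gene into the next and probes shared by overlapping genes stay open, as untested.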
